A study of Mus musculus with 2 samples.

How the data were processed

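Single-cell gene expression was measured in 2 spleen libraries, 1 of conventional T cells (Tconv) and 1 of regulatory T cells (Treg), prepared with the 10x Genomics kit for gene expression and T cell receptor sequences. The mice were BALB/c animals carrying a green fluorescent protein (GFP) reporter of Foxp3, the transcription factor that defines regulatory T cells. Per the labels' protocols, conventional cells were sorted as positive for the T cell surface protein CD3 and negative for GFP; the same text stands on both samples, and the gate of the Treg sort is not given in the sources used here. The number of mice behind each library is not given either, so each group was treated as 1 sample.

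The deposited values are unnormalised UMI counts (unique molecular identifiers, 1 per captured transcript molecule) for each gene and cell barcode, in a matrix filtered to called cells per the file names. Cell Ranger 5.0 and the mouse build GRCm38 are named in the submitters' processing notes. The annotation release is not given in the sources used here. Receptor contig tables were not used here; receptor V segments were read from the gene expression counts, which cover the start of transcripts in this kit. Both matrices list 32285 genes. The Tconv library held 4954 barcodes and 21574080 UMIs, and the Treg library 7910 barcodes and 28561185 UMIs.

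Cells were kept with at least 500 genes, at most 10% mitochondrial UMIs, at least 2 UMIs over 6 T cell receptor complex genes (Cd3d, Cd3e, Cd3g, Trac, Trbc1 and Trbc2), at most 1 UMI over the 3 B cell genes Cd79a, Cd79b and Ms4a1, and no doublet call. This left 4626 cells (93.4%) of the Tconv library and 7402 cells (93.6%) of the Treg library. Doublets were called with Scrublet, as implemented in Scanpy 1.11.5, per library at an expected rate of 0.06. It marked 8 barcodes (0.161%) in the Tconv library and 3 (0.0379%) in the Treg library, so the caller did not work on these data, and doublets of 2 T cells remain among the cells.

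Counts were summed over the cells of a library and scaled to 1000000 UMIs in total (CPM). The main comparison used CD4-gated cells, with at least 1 Cd4 UMI and no UMI of Cd8a or Cd8b1, which were 2739 cells (13115325 UMIs) in the Tconv library and 3271 cells (13605555 UMIs) in the Treg library. A second comparison used all kept cells. The CD4 gate did not take all cell states alike. In the Treg library a Cd4 UMI was found in 36.9% of cluster 1 and 41.7% of naive or central-like cluster 4. It was found in 63.1% of effector or memory-like cluster 3 and 77.8% of cycling-like cluster 12. The gated Treg sums therefore give clusters 3 and 12 more weight than their cell numbers do. In Tconv clusters 1 to 4 the share ran from 61.5% to 69.8%. Ratios are Treg over Tconv, with exact conditional 95% intervals of 2 Poisson counts. Sums carry exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. All these intervals cover counting error only. With 1 library per group there is no replicate check of any difference, and no test was run between the groups. For a ratio, a group with fewer than 3 counts entered at 3 counts. Shares of cells with a UMI depend on depth, so they were also computed after each cell was thinned at random to 1700 UMIs, the 10th percentile of the shallower library rounded down to a multiple of 100. Thinning left out 245 Tconv and 649 Treg cells. Ratios in thinned cells rest on fewer counts and are given without intervals, so a shift there may be counting error.

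Genes were named by a fixed rule. Among genes with at least 50 CPM in either library, other than receptor and immunoglobulin segments, these were the 15 highest and 15 lowest ratios of the CD4-gated comparison and the 8 highest and 8 lowest of the whole-library comparison. Up to 4 measured members of each gene list with the largest absolute log2 ratio, the 5 leading genes of each cluster, and Foxp3, Cd4, Cd8a, Cd8b1 and Xist were named as well. Some cluster genes are not reported here. The few other genes named were chosen after their values were seen: Cd3e, Nkg7 where it is set beside the clusters, the raised markers of the class II cluster, Il21, Trbv13-2, Trbv20, Tbx21, Rps27l, Trav11, Traj18, the genes compared in cells with and without Foxp3, and the neighbouring genes. The 17 gene lists covered Treg-associated genes, genes lower in Treg than in Tconv cells, naive and central cell genes, effector Treg genes, effector and memory T cell genes, follicular helper genes, cytokine genes, TNF receptor and NF-kB genes, IL-2 and STAT5 target genes, T cell receptor response genes, interferon-stimulated genes, cell cycle genes, immediate early and stress genes, cytotoxicity genes, chemokine receptor and homing genes, glycolysis genes and cytosolic ribosomal protein genes. A member was measured with at least 5 CPM in either library, and was counted as higher or lower with a ratio of at least 1.5 in that direction and a counting interval that left out 1. A list's median log2 ratio was set among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test.

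Each library was clustered alone with the Leiden method (leidenalg 0.10.2) on 2000 variable genes without receptor segments, 30 principal components, 15 neighbours and a resolution of 0.6. A cluster was named after a cell type only with at least 3 raised markers from the 17 fixed marker lists and leading genes that did not speak against the name. A cell was assigned to a Trbv or Trav segment, the variable parts of the receptor beta and alpha genes, when a single segment had the highest count and at least 2 UMIs. The total variation distance between libraries is the smallest share of cells that would have to be reassigned to make the usages equal. It is above 0 from counting alone and was not compared with a spread between animals. Gene positions come from the GENCODE annotation of GRCm38, the build named in the submitters' notes; all 302 gene identifiers looked up were found in it.

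The filters, gates, lists, named-gene rule and alternative settings were set before the data were examined. The exception was leaving out 4 kinds of clusters, which was chosen after seeing the data, as were the set of close pairs in the ribosomal comparison and the test of counting chance for Foxp3. The barcodes with B cell UMIs were added as a Foxp3 background outside the planned ones. The alternatives covered other scalings, filters, gates, depth, list minimums and cluster resolutions. The sums, ratios and list percentiles were tested on simulated data for the CD4-gated comparison, drawn from the Tconv means at the libraries' depths with 200 genes altered. All 50 genes at each of the folds 4, 2, 0.5 and 0.25 were called in the right direction (100%), as were 0.0819% of 8543 unaltered genes in either direction. The interval held the true ratio for 95.6% of 8743 genes. The simulated counts had Poisson spread alone, so the test says nothing of spread between animals. Both simulated libraries shared the same means apart from the altered genes. The test therefore does not cover a shift of the median of all genes, which was 0.21 on the log2 scale in the real CD4-gated comparison. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.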

Results

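Spleen T cells of BALB/c Foxp3-GFP reporter mice were profiled cell by cell as 1 library of GFP-negative conventional T cells (Tconv) and 1 library of regulatory T cells (Treg), the cells that restrain immune responses. After filtering, the Tconv library held 4626 cells with a median of 4271 UMIs and 1580 genes per cell. The Treg library held 7402 cells with a median of 3221.5 UMIs and 1428 genes. At equal depth the order of gene numbers turned round, with a median of 811 genes in thinned Tconv cells and 910 in thinned Treg cells. The total sequenced depth was 21574080 UMIs for Tconv and 28561185 UMIs for Treg. Each group is 1 library, so every difference below is a difference between these 2 libraries without a replicate check, and the intervals in parentheses are 95% intervals of counting error. Xist, the transcript of the inactive X chromosome, was present in the CD4-gated cells of both libraries, at 391 CPM in Tconv and 488 CPM in Treg.

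Foxp3, the transcription factor that defines regulatory T cells and drives the reporter, was abundant in the Treg library and close to absent from the Tconv library. It was not found in every Treg cell. Foxp3 (ENSMUSG00000039521, protein-coding, GRCm38 chromosome X, 7573644 to 7595245) stood at 579 CPM (567 to 592) in CD4-gated Treg cells and at 5.34 CPM (4.16 to 6.74) in CD4-gated Tconv cells, a ratio of 109 (85.8 to 139). A Foxp3 UMI was found in 5266 of 7402 Treg cells, or 71.1% (70.1 to 72.2), and in 81 of 4626 Tconv cells, or 1.75% (1.39 to 2.17). After thinning to 1700 UMIs the shares were 54.7% in Treg and 0.776% in Tconv cells, and the ratio of CPM in thinned cells was 78.1. The planned background, Tconv cells with a CD8 but no Cd4 UMI, had Foxp3 in 1 of 64 cells, or 1.56% (0.0396 to 8.40), at a median of 3883.5 UMIs against 4271 in all Tconv cells. In the Treg library the same gate held Foxp3 in 123 of 154 cells, or 79.9% (72.7 to 85.9), so it was not a gate of Foxp3-negative cells. Barcodes with at least 3 B cell UMIs and under 2 T cell UMIs, which had been filtered out, had Foxp3 in 1 of 39 in Tconv, or 2.56% (0.0649 to 13.5), and in 1 of 16 in Treg, or 6.25% (0.158 to 30.2). The Treg share lay above these intervals, while with so few cells the background of the Tconv share stayed unsettled.

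CD4-gated Treg cells stood apart from Tconv cells by Foxp3, by other genes of the Treg-associated list such as Ctla4, Tigit and Tnfrsf9, and by genes of effector regulatory cells such as Itgae and Klrg1. Tconv cells in turn held more of the genes of naive cells, of the helper ligand Cd40lg, and of Cxcr6, Ccl5 and Id2, while other genes of memory cells were higher in Treg cells. The 15 highest genes with at least 50 CPM stood 21.8-fold or more above Tconv. Besides Foxp3 these included the inhibitory receptors Ctla4 (ratio 34.8, 28.3 to 43.3) and Tigit (31.3, 24.1 to 41.4), the high-affinity interleukin-2 receptor chain Il2ra (27.1, 22.4 to 32.9), and the Ikaros family transcription factors Ikzf2 (41.2, 35.4 to 48.2) and Ikzf4 (24.5, 17.0 to 36.6). The highest ratio was that of Cyp4f18, a cytochrome P450 enzyme of leukotriene breakdown, at 0.915 CPM in Tconv and 167 CPM in Treg (182, 104 to 353). Penk, which encodes the opioid peptide precursor proenkephalin, followed at 0.915 and 113 CPM (124, 70.5 to 240). Members of the effector regulatory list were also near the top: the integrin chain Itgae at 108 CPM against 0.991 CPM (109, 63.5 to 205) and Klrg1 at 142 CPM against 1.91 CPM (74.3, 50.2 to 115). The relaxin family hormone gene Rln3 (44.8, 32.1 to 64.6), Swap70 (31.6, 20.7 to 50.8), Ly6a (27.9, 22.5 to 34.9), the TNF receptor family member Tnfrsf9 (23.4, 18.6 to 29.9) and Cd83 (21.8, 16.3 to 29.9) completed the 15. Cyp4f18 (ENSMUSG00000003484) lies on chromosome 8 at 71988482 to 72009626, Penk (ENSMUSG00000045573) on chromosome 4 at 4133531 to 4138819 and Itgae (ENSMUSG00000005947) on chromosome 11 at 73090583 to 73147446, each annotated as protein-coding on GRCm38. In thinned cells the ratio of Penk was 65.8, that of Ctla4 21.9, that of Ly6a 14.1 and that of Ikzf4 37.2. Without the class II cluster the ratio of Ly6a was 65.0 and that of Cd83 32.8, without the NKT-like cluster that of Tnfrsf9 was 39.5, and without the B cell filter that of Penk was 53.2.

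**Figure D1:**
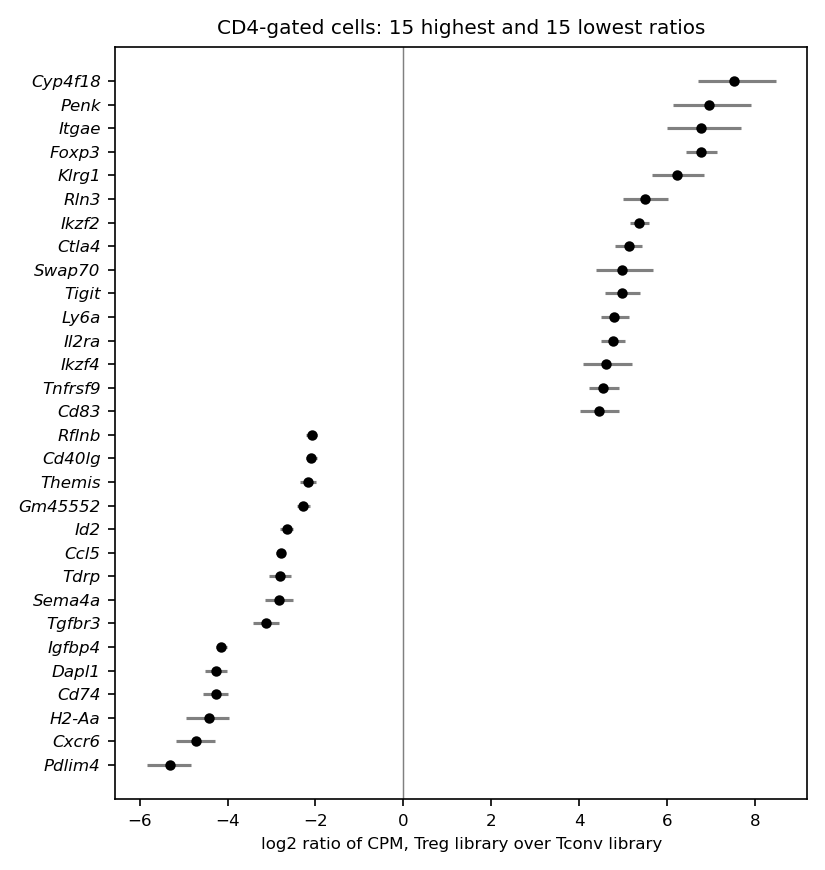
Log2 ratio of CPM, Treg library over Tconv library, of the 15 highest and 15 lowest genes with at least 50 CPM in CD4-gated cells; points are the ratios, lines their 95% counting intervals, 1 library per group. The ratios run from 7.51 for Cyp4f18 to -5.31 for Pdlim4.

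The 15 lowest genes in the Treg library were of several kinds, and included the naive T cell genes Igfbp4 and Dapl1, genes of memory and innate-like T cells, and class II genes. Igfbp4, which encodes an insulin-like growth factor binding protein, stood at 669 CPM in Tconv and 37.9 CPM in Treg (0.0566, 0.0517 to 0.0619), and Dapl1 at 202 and 10.5 CPM (0.0520, 0.0436 to 0.0615). The lowest ratio was that of the PDZ and LIM domain gene Pdlim4, at 102 and 2.57 CPM (0.0252, 0.0175 to 0.0352). Cd40lg, through which helper T cells license B cells and dendritic cells, was at 208 CPM in Tconv and 48.7 CPM in Treg (0.234, 0.215 to 0.255), and Themis, a factor of T cell development, at 112 and 24.8 CPM (0.223, 0.197 to 0.251). Tgfbr3 (0.115), Sema4a (0.141), Tdrp (0.144) and Rflnb (0.235) were lower as well. The same held for Gm45552 (0.207), annotated as antisense and therefore uncertain, since the strand setting of the counting is not given in the sources used here. Of the genes of memory and innate-like T cells, the 15 lowest held the chemokine receptor Cxcr6 (0.0380, 0.0276 to 0.0510), the chemokine Ccl5 at 536 and 77.3 CPM (0.144, 0.135 to 0.154) and the transcription regulator Id2 (0.159, 0.143 to 0.176). Without the NKT-like cluster of the Tconv library the ratio of Cxcr6 was 0.104, and in thinned cells that of Cxcr6 was 0.0185 and that of Ccl5 0.0876. Ccl5 was concentrated in the 74 cells of Tconv cluster 8. Over all kept cells it stood at 32223 CPM there, 310 CPM in the other Tconv cells and 79.0 CPM in Treg cells. Its ratio in CD4-gated cells without cluster 8 was not computed. The class II antigen presentation genes Cd74 (0.0518, 0.0422 to 0.0629) and H2-Aa (0.0465, 0.0327 to 0.0645) owed their place to the CD4-gated cells of 1 Tconv cluster. That cluster had 22 cells, 68.2% of them with a Cd4 UMI, and without it the ratios were 1.46 and 1.25. Without the CD4-gated cells of the Treg cluster with little Foxp3, Pdlim4 stood at 0.0102 and Dapl1 at 0.0312. That cluster had 53 cells, 54.7% of them with a Cd4 UMI. With at least 2 Cd4 UMIs the ratio of Pdlim4 was 0.0389. Pdlim4 (ENSMUSG00000020388, chromosome 11, 54054928 to 54069014) and Igfbp4 (ENSMUSG00000017493, chromosome 11, 99041244 to 99054392) are protein-coding.

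The Treg-associated list had 19 of 19 measured members higher in the Treg library. Its median log2 ratio of 4.33, 4.12 above that of all genes, lay at percentile 100 among random lists. Lrrc32, the surface carrier of latent TGF-beta, was at 21.2 CPM in Treg and at 0.0762 CPM, a single UMI, in Tconv. The list of genes known to be lower in Treg cells had 10 of 10 members lower, with a median of -1.80 (-2.01 relative to all genes) at percentile 0. The T cell growth factor Il2 stood at 8.46 CPM in Tconv and 0.220 CPM, 3 UMIs, in Treg (0.0261, 0.00529 to 0.0781), and the phosphodiesterase Pde3b at 24.8 and 1.10 CPM (0.0445, 0.0246 to 0.0745). In thinned cells the ratio of Il2 was 0.104 and that of Lrrc32 20.1. There the Treg sum of Il2 and the Tconv sum of Lrrc32 entered at the floor of 3 counts, so these ratios do not show the effect of depth. Without the Treg cluster with little Foxp3 the ratio of Pde3b was 0.0210. The median of all genes was itself 0.21 above 0 on the log2 scale under scaling to total UMIs, and 0.02 both with median-of-ratios scaling and with totals that left out ribosomal, mitochondrial and receptor genes; list medians are therefore also given relative to all genes.

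Effector regulatory T cell genes stood higher in the Treg library, in 20 of 21 measured members, with a median log2 ratio of 2.04 (1.82 relative to all genes, percentile 100). Gzmb, the protease granzyme B, was at 34.4 CPM in Treg and 0.839 CPM in Tconv (41.0, 22.7 to 82.7), and the skin and tissue Treg chemokine receptor Ccr8 at 19.1 and 0.839 CPM (22.8, 12.5 to 46.2). The exception was Tbx21, the type 1 lineage factor, at 6.25 CPM in Treg and 23.8 CPM in Tconv (0.263, 0.204 to 0.335). In thinned cells the ratio of Gzmb was 9.70. Itgae and Tnfrsf9 of this list are also on the Treg-associated list.

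TNF receptor and NF-kB genes were higher in the Treg library in 11 of 11 members (median 1.29, 1.08 relative to all genes, percentile 100), led by Tnfrsf9, Tnfrsf4 (20.2, 17.9 to 22.8), Tnfrsf1b (4.93, 4.10 to 5.96) and Tnfrsf18 (3.97, 3.75 to 4.22). Targets of interleukin-2 and STAT5 signalling were higher in 8 of 11 members and lower in 0, with a median of 1.62 (1.40 relative to all genes, percentile 100). Among them were Pim1, a kinase (3.89, 3.69 to 4.10), and Nfil3 (4.15, 2.92 to 6.04), the latter at 2.70 in thinned cells. Both lists overlap with the Treg-associated one, which also holds Tnfrsf9, Tnfrsf4, Tnfrsf18, Il2ra, Il2rb and Socs2. Of the 10 follicular helper genes 6 were measured, and 5 of these were higher (median 1.77, 1.56 relative to all genes, percentile 100), including the follicle-homing receptor Cxcr5 (4.37, 3.15 to 6.18), the inhibitory receptor Pdcd1 (4.10, 3.39 to 4.999), Tox2 (3.51, 2.23 to 5.70) and Tox (3.32, 2.98 to 3.70). With no CPM minimum for members the median of this list was 0.99.

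Chemokine receptor and homing genes went both ways, with 9 of 17 higher and 1 lower in the Treg library (median 0.61, 0.40 relative to all genes, percentile 100). Besides Itgae and Ccr8, the mucosal homing receptor Ccr6 was higher, at 62.5 against 5.18 CPM (12.05, 9.41 to 15.7), while Cxcr6 was the lower one. The median was 0.23 in thinned cells and 0.25 over all kept cells, against an all-gene median of 0.20 in both, so little of the list difference was left there. Without the NKT-like cluster it was 1.02, and without the class II cluster the ratio of Ccr6 was 21.95.

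Naive and central cell genes were lower in the Treg library in 8 of 12 members and higher in 0 (median -1.05, -1.27 relative to all genes, percentile 0). The transcription factors Tcf7 (0.353, 0.334 to 0.373) and Lef1 (0.406, 0.390 to 0.423), both kept on in quiescent T cells, stood beside Igfbp4 and Dapl1 as the members that differed most. This list largely repeated that of genes lower in Treg cells, which held 7 of its 12 members and 7 of the 8 counted as lower. Effector and memory T cell genes split, with 5 of 15 higher and 8 lower (median -0.64, -0.85 relative to all genes, percentile 0). The calcium-binding protein gene S100a6 was at 195 CPM in Tconv and 1162 CPM in Treg (5.96, 5.71 to 6.21), whereas Cxcr6, Ccl5 and Id2 were lower. In thinned cells the ratio of S100a6 was 3.30. With members at 20 CPM or more alone, the median of this list was 0.21.

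Cytotoxicity genes were lower in the Treg library in 6 of 9 measured members and higher in 2 (median -1.99, -2.21 relative to all genes, percentile 0). The receptor Klrd1 had 0 UMIs in CD4-gated Treg cells against 15.6 CPM in Tconv cells, and the death ligand Fasl stood at 3.75 and 23.9 CPM (0.157, 0.114 to 0.212), while Gzmb was higher. Without the NKT-like cluster the ratio of Fasl was 0.284. Of the cytokine genes only 6 of 13 were measured, 1 higher and 3 lower (median -0.76, -0.98 relative to all genes, percentile 0.01). Il4, the type 2 cytokine, was at 1.32 CPM in Treg and 13.6 CPM in Tconv (0.0975, 0.0565 to 0.159), and Ifng, interferon gamma, at 4.78 and 14.8 CPM (0.323, 0.240 to 0.430). Ebi3, a subunit of interleukins 27 and 35, was at 29.8 CPM in Treg and 3.05 CPM in Tconv (9.76, 7.04 to 13.9). With members at 20 CPM or more alone the cytokine median was 0.50, and without the NKT-like cluster the ratio of Il4 was 0.188. In thinned cells the ratio of Ebi3 was 6.07, and over all kept cells that of Il4 was 0.0412.

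T cell receptor response genes were higher in 3 of 11 members and lower in 0 (median 0.50, 0.29 relative to all genes, percentile 98.9). The nuclear receptor Nr4a1, induced by receptor signalling, stood at 63.4 CPM in Treg and 12.5 CPM in Tconv (5.07, 4.28 to 6.02), followed by Irf4 (4.62, 3.33 to 6.55), Egr2 (1.74, 1.25 to 2.45) and Cd5 (1.49, 1.43 to 1.55). With members at 20 CPM or more alone the median was 0.22, near the 0.21 of all genes, and in thinned cells the ratio of Irf4 was 2.58. Interferon-stimulated genes were higher in 7 of 12 members and lower in 0 (median 0.69, 0.48 relative to all genes, percentile 99.9), led by Ifi27l2a at 2154 against 624 CPM (3.45, 3.37 to 3.54) and Isg20 (2.64, 2.27 to 3.09). Over all kept cells that median was 0.33, and Ifit3, at 1.75 (1.17 to 2.66) in CD4-gated cells, was at 0.851.

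Cell cycle genes were higher in 11 of 15 members and lower in 0 (median 1.42, 1.21 relative to all genes, percentile 100), with the ubiquitin-conjugating enzyme Ube2c (6.77, 5.09 to 9.15), the proliferation marker Mki67 (5.35, 4.34 to 6.65), Ccna2 (4.69, 3.28 to 6.87) and Birc5 (3.43, 2.72 to 4.37) in front. The cycling-like clusters, where such genes were raised, held 36 Treg cells (median 13696.5 UMIs) and 16 Tconv cells (median 11900.5 UMIs). The CD4 gate gave that Treg cluster more weight than its cell number does. Counting intervals treat UMIs of 1 cell as separate draws, so they are too narrow where few cells carry a gene. How much of the list difference these clusters carried is not given here. When each cell counted alike, as the mean of per-cell CPM, the list median was 0.81 against 0.22 for all genes. In thinned cells it was 0.21 against 0.20 for all genes, and Ccna2 was at 1.32, Birc5 at 1.85 and Ube2c at 3.97. Thinning cuts the UMI-rich cycling-like cells to the depth of all other cells. The thinned ratios of these genes also rest on fewer counts and have no intervals. The thinned values therefore cannot show whether the list differs between the libraries.

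Immediate early and stress genes lay on both sides, 1 of 13 higher and 2 lower. Their median of -0.02 was -0.23 relative to all genes, at percentile 1.83. Its sign differed between settings, but in the settings where it moved or turned round it stayed below the median of all genes. Dusp1, a phosphatase, was higher (2.498, 2.32 to 2.70) and the heat shock genes Hspa1a (0.418, 0.395 to 0.442) and Hspa1b (0.476, 0.442 to 0.513) were lower. Glycolysis genes stood near the all-gene median (0.20, -0.01 relative to all genes, percentile 56.5), with 1 of 14 higher, the glucose transporter Slc2a3 (4.71, 4.06 to 5.48). Their median was 0.01 with median-of-ratios scaling.

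Cytosolic ribosomal protein genes were lower as a family, with 76 of 80 below a ratio of 1 and a median of -0.39 (-0.60 relative to all genes, percentile 0). Among them, 15 were lower by at least the set ratio and 1, Rps27l, was higher. The largest differences were in genes of small proteins: Rps29 at 7404 CPM in Tconv and 3284 CPM in Treg (0.444, 0.439 to 0.449), Rps28 (0.494, 0.488 to 0.5003), Rps21 (0.544, 0.538 to 0.551) and Rps27 (0.601, 0.596 to 0.607). Ribosomal protein genes made up 34.7% of UMIs in Tconv and 26.6% in Treg cells. Many of them have near-identical pseudogenes, so single values are uncertain where the counting could have divided UMIs among copies.

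**Figure D2:**
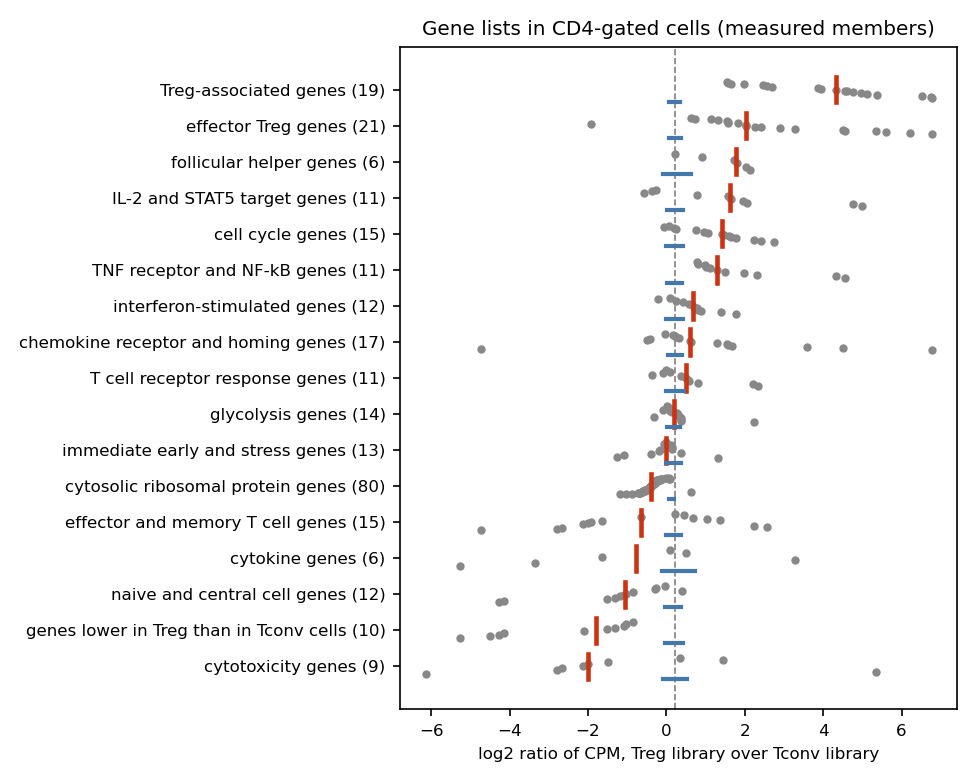
Log2 ratio of CPM, Treg library over Tconv library, of the measured members of each fixed gene list in CD4-gated cells (grey points, number of members in parentheses), with list medians (red bars), the central 95% of medians of 10000 matched random lists (blue lines) and the median of all genes (dashed). Medians run from 4.33 for Treg-associated genes to -1.99 for cytotoxicity genes.

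Without the CD4 gate Cyp4f18, Penk, Foxp3 and Itgae led in the Treg library, and Pdlim4, Cxcr6, Dapl1 and Igfbp4 led in the Tconv library. Over all kept cells, the genes that differed most were nearly those of the CD4-gated cells. Cyp4f18 (140, 97.49 to 210), Penk (127, 80.0 to 214), Foxp3 (113, 93.4 to 138), Itgae (87.7, 57.8 to 140), Klrg1 (69.6, 50.4 to 99.1), Rln3 (41.9, 32.3 to 55.5), Ikzf2 (34.1, 30.5 to 38.3) and Ctla4 (31.3, 26.5 to 37.1) had the 8 highest ratios. Pdlim4 (0.0202, 0.0151 to 0.0265), Cxcr6 (0.0285, 0.0232 to 0.0348), Dapl1 (0.0540, 0.0478 to 0.0609), Igfbp4 (0.0573, 0.0537 to 0.0611), Cd74 (0.0785, 0.0684 to 0.0899), Tgfbr3 (0.119, 0.103 to 0.139), Ccl5 (0.121, 0.115 to 0.126) and Id2 (0.126, 0.117 to 0.136) had the 8 lowest. All 16 also belonged to the 30 extremes of the CD4-gated cells.

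CD8 T cells were nearly absent from both libraries by their transcripts, although the stated gate of the Tconv sort was CD3 with no mention of CD4. Cd8a, the obligate chain of the CD8 receptor, had 1 UMI in 4626 Tconv cells and 1 UMI in 7402 Treg cells. Cd8b1, the partner chain, had a UMI in 4.54% (3.96 to 5.18) of Tconv and 4.46% (3.999 to 4.95) of Treg cells, and in 2.28% and 2.32% of thinned cells, so it did not separate the libraries. Cells with a CD8 but no Cd4 UMI made up 1.38% (1.07 to 1.76) of Tconv cells and 2.08% (1.77 to 2.43) of Treg cells, or 1.32% and 1.67% after thinning. A Cd4 UMI was found in 62.4% (61.0 to 63.8) of Tconv and 46.6% (45.4 to 47.7) of Treg cells. The thinned shares were 34.5% and 28.1%, and Cd4 over all kept cells stood at 256 CPM in Tconv and 197 CPM in Treg (0.772, 0.743 to 0.802).

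The same common Trbv segments led in both libraries. Among the common segments Trbv4 was lower in the Treg library, and families that superantigens remove in this strain were rare in both but less so in Treg cells. A Trbv segment was assigned in 2289 of 2739 CD4-gated Tconv cells (83.6%) and 2708 of 3271 Treg cells (82.8%). Trbv19, Trbv13-2, Trbv31, Trbv13-1, Trbv20 and Trbv1 were the most used in both, from 12.9% for Trbv19 to 9.87% for Trbv1 in Tconv. Among segments with at least 1% in either library, the highest ratios were those of Trbv29, at 0.437% (0.210 to 0.802) in Tconv and 1.51% (1.09 to 2.05) in Treg, of Trbv3, at 0.786% (0.467 to 1.24) and 1.81% (1.34 to 2.39), and of Trbv16, at 0.699% (0.400 to 1.13) and 1.18% (0.810 to 1.66). The lowest were those of Trbv4, at 6.25% (5.29 to 7.32) and 4.32% (3.59 to 5.16), Trbv13-3, at 7.21% (6.18 to 8.35) and 5.91% (5.05 to 6.86), and Trbv13-1, at 12.4% (11.04 to 13.8) and 11.1% (9.96 to 12.4). The beta families that endogenous superantigens delete in BALB/c mice (Trbv26, Trbv12-1, Trbv12-2, Trbv16 and Trbv15) together took 28 Tconv cells, or 1.22% (0.814 to 1.76), and 69 Treg cells, or 2.55% (1.99 to 3.21). Within them Trbv15 was at 0.306% and 0.849%, Trbv12-1 at 0.0437% and 0.222%, Trbv12-2 at 0.131% and 0.148%, and Trbv26 at 0.0437% and 0.148%. The total variation distance of Trbv usage was 6.37%. In CD4-gated cells the counting intervals of the ratios of Trbv16 (1.69, 0.901 to 3.30), Trbv13-3 and Trbv13-1 included 1. Over all kept cells that of Trbv16 did not (2.10, 1.27 to 3.61), and the ratio of Trbv29 was 2.19 (1.45 to 3.38), against 3.47 (1.71 to 7.76) in CD4-gated cells. Without the NKT-like cluster Trbv13-1 stood at 0.958 (0.807 to 1.14) and was no longer among the 3 lowest, Trbv20 took its place at 0.910 (0.761 to 1.09), and Trbv13-2 was higher in Treg (1.21, 1.03 to 1.43), whereas over all kept cells it was at 0.915 (0.821 to 1.02).

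Alpha segments could be assigned in fewer cells, 1621 Tconv (59.2%) and 1796 Treg (54.9%), and the total variation distance of their usage was 12.3%. Fewer cells over more segments, 60 seen against 24 for Trbv, raise such a distance by counting alone. It therefore does not show a larger difference in alpha than in beta usage. Among segments with at least 1% in either library, Trav7-1 (0.679% in Tconv, 1.78% in Treg), Trav6-1 (0.494% and 1.17%) and Trav10n (0.864% and 1.78%) had the highest ratios, and Trav14n-3 (1.91% and 0.445%), Trav19 (1.42% and 0.612%) and Trav6d-5 (1.42% and 0.780%) the lowest. Over all kept cells the ratios of Trav7-1 (1.56, 0.949 to 2.65), Trav10n (1.502, 0.917 to 2.52) and Trav19 (0.789, 0.487 to 1.28) had intervals that included 1, as had that of Trav6d-5 in CD4-gated cells (0.549, 0.261 to 1.11). Trav segments exist in near-identical copies, marked d and n, so counts of single members are uncertain.

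**Figure D3:**
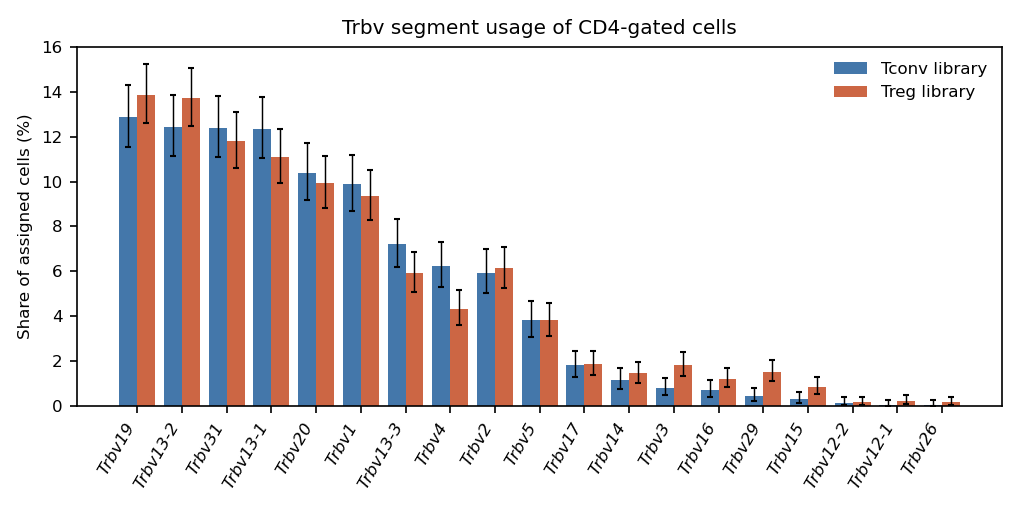
Share of CD4-gated cells with an assigned beta segment that used each Trbv segment, in percent, in the Tconv library (blue, 2289 cells) and the Treg library (orange, 2708 cells), for segments with at least 1% in either library and the superantigen-deleted families; error bars are exact 95% binomial intervals. Trbv29, Trbv3 and Trbv4 have intervals that do not overlap between the libraries.

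Within the Tconv library, cells ranged from naive or central states to effector, innate-like and activated states. Cluster 1 (24.8% of cells) was effector or memory-like and led by S100a4, S100a6, Itgb1, Nebl and Casp1. Cluster 3 (18.8%) was naive or central-like, with Ccr7, Lef1, Igfbp4 and Dapl1 raised and Sesn1, Usp28, Tdrp, Tent5c and Tsc22d3 leading. Cluster 2 (21.98%), led by Igfbp4, Pdlim4, Dapl1, Srm and Rbm38, and cluster 4 (13.7%), led by Itm2a, Il6st, Treml2, Klhdc2 and Actn1, had too few raised markers for a name. Cluster 5, with 367 cells (7.93%, 7.17 to 8.75), was NKT-like: it was led by Zbtb16, the lineage factor of innate-like T cells, Xcl1, Tmem273, Samd3 and Itga1, and carried raised Trav11 and Traj18, the segments of the invariant NKT receptor. A Cd4 UMI was found in 34.6% of its cells, and 4 gamma-delta markers were raised in it as well. Trav11 and Traj18 were seen in few of its cells, and over all kept Tconv cells only 1 was assigned to Trav11. Cluster 7 (2.88%) was interferon-responding-like with 7 of 7 markers raised (led by Ifit1, Isg15, Usp18, Iigp1 and Gbp10), and cluster 13 (16 cells) was cycling-like (led by Ccnb2, Birc5, Ccna2, Pclaf and Mxd3). Cluster 9 (59 cells) was led by the receptor-induced genes Nr4a1, Egr3, Egr2 and Egr1, with Id3. Cluster 11 (26 cells) was led by Edn3, Angptl2, Lag3, Ces2c and Nrn1, with Pdcd1 at 338 CPM, Cxcr5 at 141 CPM and the follicular cytokine Il21 at 113 CPM, against 8.77, 2.99 and 0.868 CPM over the library.

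Another 2 Tconv clusters stood apart by cytotoxic and by class II genes. Cluster 8 (74 cells) was led by S1pr5, Gzma, Eomes, Zeb2 and Ccl5, with Ccl5 at 32223 CPM against 655 CPM over the library. A Cd4 UMI was found in 48.6% of its cells, so it was not named after CD8 T cells despite raised genes shared with them. It also had 7 of 9 effector or memory markers raised and was left unnamed. Cluster 12 (22 cells) was led by H2-Eb1, Cd74, H2-Aa, Ctsh and Sdc4. Its raised markers came from several lineages, among them 4 B cell genes (Cd79b, Ighm, H2-Aa and Cd74), 3 dendritic genes (Flt3, Siglech and Itgax) and 3 monocyte or macrophage genes (Fcer1g, Cst3 and Tyrobp). Its median of 7061.5 UMIs lay above the 4271 of the library and its Cd3e level at 600 CPM against 1335 CPM, and without a working doublet call it was not named as a cell type. Clusters 6 (led by AY036118, Gm26917, Lars2, Snhg20 and Gm42418) and 10 (led by Gm16565, Kcnq1ot1, Dennd1a, Slc35e2 and 2010016I18Rik) had low UMI counts, with medians of 1780 and 1191.5, and were left unnamed.

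Treg cells also ranged from naive or central to effector states. Smaller groups were marked by Penk and Ccr8, by Lta and Socs1 together with interferon genes, and by cell division. Within the Treg library, cluster 4 (12.1%) was naive or central-like (led by Tubb2a, Aven, Slc35d1, Ctsl and Atp1b1) and cluster 3 (12.5%) effector or memory-like, with 8 of 9 markers raised (led by Lgals3, S100a6, Ccr2, S100a4 and Lgmn). Cluster 7 (402 cells) was led by Ccr8, Ccl5, Klrg1, Epcam and Tnfrsf9 and held the highest Penk, at 1236 CPM against 110 CPM over the library. Cluster 10 (108 cells) was led by Gpr25, Serpinb1a, Tmem176a and Tmem176b, with Ikzf2 at 63.9 CPM against 522 CPM over the library. It was given no name, although 6 of 9 effector or memory markers were raised in it. Cluster 6 (452 cells) was led by the cytokine gene Lta, the signalling inhibitors Socs1 and Socs2, Isg15 and Myc, and had all 7 interferon markers raised. Of these markers only Isg15 was among the 10 leading genes of the cluster, which also held Socs1, Socs2, Myc and Il2ra of the IL-2 and STAT5 list. Cluster 5 (11.04%) was led by Sapcd1, Cst7, Tbc1d4, Cd83 and Tnfrsf9, cluster 2 (17.8%) by Itgb1, Nrp1, Hspa1a, Il7r and Tcf7, and cluster 1 (25.02%) by Atp1b1, Satb1, Kbtbd11, Actn1 and Gm20400. Cluster 12 (36 cells) was cycling-like (led by Mxd3, Nuf2, Pimreg, Esco2 and Pbk). Clusters 8 (led by Kcnq1ot1, Bach2, Tmem131, Ahcyl2 and Nin) and 9 (led by Kcnq1ot1, Lncpint, 2010016I18Rik, St8sia4 and Kif13b) were unnamed, and cluster 9 had a median of 1044 UMIs.

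A Foxp3 UMI was found in 57.4% to 91.9% of the cells of 11 Treg clusters. Cluster 11 (53 cells, 0.716% of the library) differed, with Foxp3 in 15.1% (6.75 to 27.6) at a median of 4921 UMIs. It was naive or central-like and led by Pdlim4, Dapl1, Igfbp4, Tgfbr3 and Tdrp. Igfbp4 stood there at 1090 CPM, against 36.6 CPM over the Treg library and 638 CPM over the Tconv library, and Ikzf2 at 11.5 CPM against 522 and 15.3 CPM. Cluster sizes are not compared between the libraries, which were clustered alone.

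**Figure D4:**
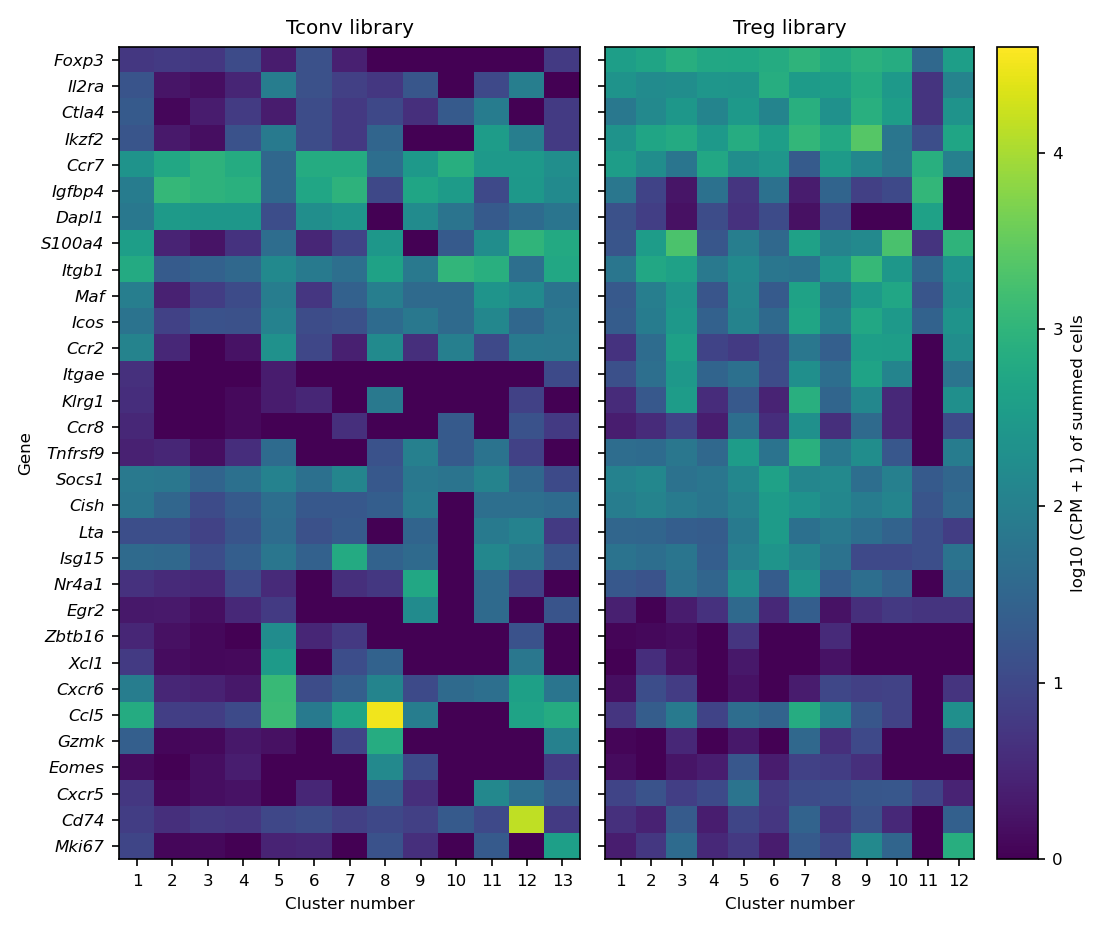
Level of selected genes (rows) in the clusters of the Tconv library (left, 13 clusters) and the Treg library (right, 12 clusters), as log10 of summed CPM plus 1. Foxp3 is low in Treg cluster 11, where Igfbp4 and Dapl1 are high, and Zbtb16, Xcl1 and Cxcr6 are high in Tconv cluster 5.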

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

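Leaving out single clusters was chosen after seeing the data; the other alternatives were planned. The Foxp3 ratio stayed above 1 under each of its 14 alternatives, 13 within the counting interval, and was 78.1 in thinned cells. The share of Treg cells with a Foxp3 UMI was 54.7% in thinned cells, 74.0% over CD4-gated cells and 74.4% with at least 1000 genes and at most 5% mitochondrial UMIs, and in Tconv cells it was 0.776% after thinning. The share of CD8-gated Treg cells was 1.67% after thinning. The Trbv distance was 8.64% with at least 2 Cd4 UMIs, a gate that keeps fewer cells, which by itself raises such a distance. Resolution 0.3 gave 7 Treg clusters instead of 12.

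The naive and central median was -1.25 with totals that left out ribosomal, mitochondrial and receptor genes and -1.25 with median-of-ratios scaling. The effector Treg median was 1.84 and 1.84 under these scalings, 2.41 with at least 2 Cd4 UMIs and 2.38 without the NKT-like cluster. These scalings lowered the median of all genes by a like amount. For members at 20 CPM or more, the medians of effector and memory genes (0.21), cytokine genes (0.50) and immediate early and stress genes (0.047) turned positive. The last list was also positive with at least 2 Cd4 UMIs (0.058), over all kept cells (0.000203), as mean of per-cell CPM (0.11), in thinned cells (0.084), without the NKT-like cluster (0.039) and without the class II cluster (0.033). In each of these settings it lay below the median of all genes, which ran from 0.20 to 0.23. Ratios turned round for Cd74 (1.46) and H2-Aa (1.25) without the class II cluster, and for Ifit3 over all kept cells (0.851) and in thinned cells (0.856). Where the setting does not show the cause by its construction, the cause was not tested. Over all settings, 68 list medians and 195 gene ratios moved outside the main value's counting interval without turning round. Another 9 and 4 turned round, and 195 and 893 did neither. The counting error of the alternative value itself was not taken into account.

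No paired analysis was possible because each group is 1 library. The gate by CD4-like and Treg-like clusters was not run, since no Tconv cluster had 3 raised CD4 markers. Depth limited genes near 1 UMI in a library, such as Lrrc32, Il2 and Cd8a, and each share of cells with a UMI.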

Other observations

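The 81 Tconv cells with a Foxp3 UMI held more of some genes of the Treg-associated list than the other Tconv cells, while most members were not shown to be higher. Of the 18 members other than Foxp3, 7 had a ratio with its interval above 1, 1 lay below 1, and the intervals of 10 included 1. Among these 10, Lrrc32 and Entpd1 had 0 UMIs in the 81 cells, Nrp1 had 1, and Tigit and Tnfrsf9 had 2. Such counts are too low to settle a difference. Among the higher ones were Ikzf2 at 74.0 against 14.1 CPM (ratio 5.24, 3.47 to 7.65), Gpr83 at 34.5 against 7.57 CPM (4.56, 2.44 to 7.89), Ctla4 at 27.1 against 6.64 CPM (4.09, 1.99 to 7.55) and Il2ra at 29.6 against 12.4 CPM (2.38, 1.21 to 4.23). These levels lay below those of the Treg library, where Ikzf2 was at 522 CPM and Ctla4 at 220 CPM over all kept cells. Il2rb was lower in them (0.586, 0.400 to 0.829), and Izumo1r differed little (1.13, 0.858 to 1.45).

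Some of the genes with the largest ratios were neighbours in the genome. Among the top 50 genes of the CD4-gated comparison there were 5 pairs within 100 kb, against a median of 0 and a maximum of 4 in 1000 random lists. The pairs were Gpr83 with Izumo1r, Ctla4 with Icos, Ift80 with Trim59, S100a6 with S100a4, and Tnfrsf4 with Tnfrsf18. Ift80 and Trim59 lie close enough that shared reads stay possible.

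The 3 patterns below were picked after the values were seen; the test of counting chance for Foxp3 and the close-pair comparison were chosen after the result was seen, and the outcomes of the other tests were written down before they were run.

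No Foxp3 UMI was found in 28.9% of the Treg library's cells. Poisson counting at each cell's UMIs and at 1 Foxp3 level per cluster gave 21.1%. Counting chance of this kind as the whole cause was argued against, since the observed share was higher by 7.74 percentage points (6.71 to 8.79). Conventional cells in the sort as the whole cause were argued against too: over 28 genes of the Treg-associated and lower-in-Treg lists, the cells without Foxp3 lay at a median position of 0.196 (quartiles 0.0686 and 0.417), where 0 is the level of Treg cells with Foxp3 and 1 that of the Tconv library. Their Ikzf2 was at 473 CPM, against 536 CPM in cells with Foxp3 and 15.3 CPM in Tconv cells. A spread of Foxp3 level among the cells of a cluster, which would leave more cells without a UMI, was not tested. It stays open, as do missed transcripts as part of the cause. A minority of conventional cells, such as the 53 cells of cluster 11, and cells with reporter protein but little Foxp3 RNA stay open too, since the Treg gate is not given in the sources used here.

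The lower level of ribosomal protein genes in the Treg library is not explained by fewer cells with raised naive or central markers alone. Clusters were grouped here by a looser rule than the one for names: at least 2 raised naive or central markers and under 2 effector or memory ones (Tconv clusters 2, 3 and 4, Treg clusters 1, 4 and 11). Among their CD4-gated cells (1506 Tconv and 1041 Treg cells), the ribosomal median lay at -0.33 relative to all genes (quartiles -0.46 and -0.27), with 77 of 80 genes below the all-gene median. The gap was smaller than the -0.60 of all CD4-gated cells. Within each library, clusters with at least 6 raised effector or memory markers (Tconv 1, 8, 11 and 13, Treg 3 and 10), whatever their name, lay below this group, with a ribosomal median of -0.28 against 0.19 for all genes in Tconv and -0.63 against 0.11 in Treg, so the mix of states may account for part of the pattern. A general loss of short, highly expressed transcripts was argued against too, since genes matched on transcript length and expression lay 0.57 above the ribosomal genes (quartiles 0.37 and 0.75). That match fell short in level, at a median of 1201 against 3926 CPM, but in the 27 pairs within 2-fold in both properties the difference was 0.55 (quartiles 0.44 and 0.78). A difference in cell state between regulatory and conventional cells and a difference between the 2 library preparations may both contribute and were not tested.

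NKT-like cells are a candidate source of the Cxcr6, Ccl5, Nkg7 and Id2 counts that put these genes lower in the CD4-gated Treg cells. They were not the whole source: without that cluster, the median ratio of the 4 genes was 0.181 and the ratios ran from 0.104 for Cxcr6 to 0.343 for Nkg7, against 0.0380 and 0.251 with it. Cluster 8 also carried Nkg7 and Ccl5, at 2232 and 32223 CPM. Effector or memory-like cluster 1 held Nkg7 at 155 CPM and Ccl5 at 667 CPM. That Ccl5 level was near the 655 CPM of the whole Tconv library and above the 310 CPM of the cells outside cluster 8. Cxcr6 and Id2 are not given for these clusters. A lower level of the 4 genes in regulatory cells of effector state stays open, as does the share of each state that the sorts took in.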
